A study of Homo sapiens with 12 samples.

How the data were processed

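RNA was prepared from NT2/D1 cells, and libraries were made with the Illumina TruSeq stranded mRNA kit, per the labels' protocols. The deposited table holds raw counts per gene, 1 column per library, as whole numbers that sum to a different total in each library. Per the submitters' processing notes, reads were handled with bcl2fastq, TopHat2, Subread, featureCounts and DESeq2 on the builds hg19 and GRCh37; versions, the annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here. The deposited table also gives a length for each gene, used here only to describe the libraries. Without a stated strand setting, reads of overlapping or antisense genes cannot be assigned with certainty, and genes with near-identical copies may share reads.

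Groups were taken from genotype and ATRA labels: CRISPR/Cas9 control and PRMT6 knockout, each untreated and with ATRA, 3 libraries per group. All 12 columns matched 1 sample each and all were used. Total counts ran from 25.5 to 60.4 M per library, at which 3 counts correspond to 0.128 and 0.0433 CPM. The design, the tests, the rule for named genes, the 27 gene lists and the first set of other settings were fixed before the data were examined.

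Everything below was computed from the deposited counts. Genes were kept with edgeR's filterByExpr (minimum count 10) given the 4 groups, which left 19130, and libraries were scaled by TMM. A quasi-likelihood model with 1 coefficient per group over all 12 libraries was fitted in edgeR 4.0.16 under R 4.3.3. Its F-test gave 5 contrasts: knockout against control untreated and with ATRA, ATRA against untreated in control and in knockout, and the interaction. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Every edgeR adjusted p is of this kind. The biological coefficient of variation was 0.367. Levels are CPM on TMM-scaled library sizes, as mean ± SD, and fold changes are fitted values with their standard errors. For a gene with no counts in a group, the fold is a lower bound with 3 counts over the group as the floor. With 1 to 3 counts it is a ratio of the summed counts, on the same scaled sizes, with a 95% counting interval.

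The named genes are PRMT6 and, per comparison, up to 6 genes with the largest increase and 6 with the largest decrease among those called. These had a mean of at least 5 CPM in a compared group, libraries that did not overlap between the groups, and a symbol that is not clone-based, antisense or a small RNA. Added were the 2 called members with the smallest adjusted p of each list, and every tested HOXA gene. Results of some genes that this rule names are not reported here. The lists cover pluripotency, retinoid signalling, the HOXA, HOXB, HOXC and HOXD clusters, neural progenitor, neuronal and neural crest genes, mesoderm, endoderm, trophoblast and amnion, fibroblast and epithelial genes, protein arginine methyltransferases, p53 targets and CDK inhibitors, the cell cycle, Polycomb and trithorax complexes, germline and imprinted genes, targets of WNT, of TGF-beta and BMP and of FGF and ERK signalling, interferon-stimulated, stress and cholesterol synthesis genes, and mitochondrial mRNAs. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation, which allows for members that vary together between libraries.

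Libraries were compared in pairs by a chi-square over genes with at least 20 counts in the pair. The GC content of genes came from GENCODE v44 on GRCh38, another build than that of the counts, matched by symbol for 33189 of 56638 symbols and for 97.6% of genes of at least 5 CPM. It was used for GC content and for which genes neighbour each other, and no coordinates are given. The edgeR, limma-voom and DESeq2 steps were tested on simulated data with known changed genes for each comparison, with edgeR making 4 to 12 false calls and DESeq2 47 to 58. The simulated libraries were independent draws with few changed genes, without near-identical pairs or GC trends. Recovery and false calls in the real data may therefore differ.

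Other settings fixed at that point were RLE scaling, DESeq2 1.42.0, limma-voom, no filter and a stricter filter (over 1 CPM in at least 3 libraries), a fit of the compared groups only, the replicate number as a block, a log2 fold change of at least 1, leaving out each library in turn, and for lists an estimated correlation and fry. Settings added after the data were seen were removal of each library's GC trend as an offset, summing the near-identical knockout libraries (untreated 1 and 2, ATRA 1 and 3), leaving out control untreated 2 and control ATRA 2, and thinning every library to the smallest total.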

Results

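Messenger RNA was measured in NT2/D1, a human embryonal carcinoma line that is pluripotent and differentiates, mainly along the neural lineage, when given all-trans retinoic acid (ATRA). Cells made with CRISPR/Cas9 as a control were compared with cells lacking PRMT6, an arginine methyltransferase that methylates histone H3 and other proteins. The labels name 1 knockout line only. Each genotype was sequenced untreated and after 3 days with 1 µM ATRA, with 3 libraries per group and 12 in all. Total counts were 35.8, 52.7 and 60.4 M in the untreated control, 29.8, 32.3 and 25.5 M in the untreated knockout, 32.1, 37.2 and 38.4 M in the control with ATRA, and 36, 35.4 and 38.2 M in the knockout with ATRA, in the order of replicates 1 to 3. The design asks how the transcriptome depends on PRMT6, before and after ATRA. No label says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

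Within groups, most pairs of knockout libraries were more alike than the pairs of control libraries. Knockout ATRA 1 and 3 differed by a chi-square of 1.91 per gene and knockout untreated 1 and 2 by 9.01, against 78.1 to 416 for the other pairs within a group. Control ATRA 1 and 3 differed by 87.3, less than knockout ATRA 2 from knockout ATRA 1 and 3 (118 and 122). Both near-identical pairs still differed by more than sampling noise and were counted as separate libraries. COL3A1 and DCN, chosen after their values were seen, were low in knockout untreated 3 and knockout ATRA 2. COL3A1, a fibrillar collagen, stood at 10600, 10900 and 1320 CPM (the library-size-scaled unit of edgeR) in the untreated knockout and at 10300, 1670 and 10100 CPM in the knockout with ATRA. DCN, which encodes the matrix proteoglycan decorin, stood at 22.5, 17.9 and 0.128 CPM and at 27.9, 0.264 and 26.4 CPM. GC content moved with genotype: the rank correlation of expression with GC content, relative to the mean of all libraries and across genes, which are not independent replicates, ran from -0.294 to -0.496 in the control libraries except 0.097 in control ATRA 3, and from 0.223 to 0.617 in the knockout libraries.

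PRMT6 was present in every control library and almost absent from every knockout library. Its level was 22.4, 1.94 and 8.94 CPM in the untreated control (11.1 ± 10.4, mean ± SD, n = 3) and 29.9, 15.9 and 26.8 CPM in the control with ATRA (24.2 ± 7.36, n = 3). The knockout libraries held 2 PRMT6 counts in all when untreated and 2 with ATRA, and none exceeded 0.0587 CPM. The ratio of control to knockout was 395 untreated (95% counting interval 109 to 3260) and 1250 with ATRA (347 to 10400). Such intervals, and the bounds given for genes without counts, cover counting error only. In the control, PRMT6 did not differ detectably between ATRA and untreated cells (log2 fold change 1.13 ± 0.67 SE, edgeR adjusted p = 0.351).

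**Figure D1:**
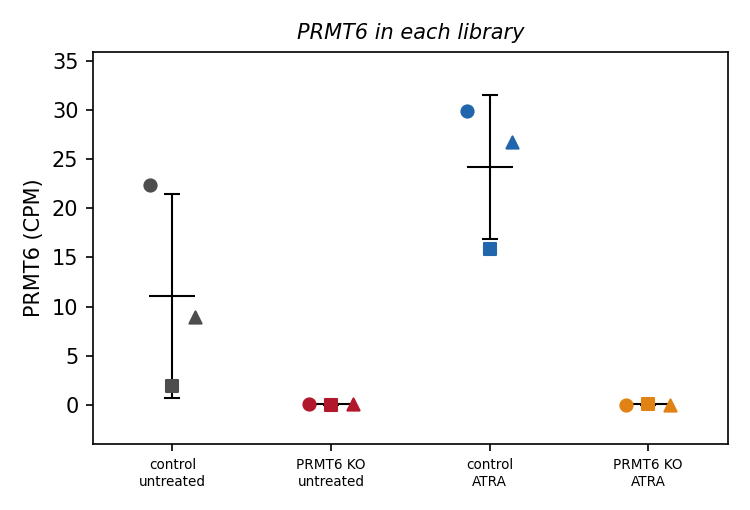
PRMT6 in each of the 12 libraries, in CPM on a linear axis; circles, squares and triangles are replicates 1, 2 and 3, horizontal lines are group means and bars are SDs (n = 3). Control libraries lie between 1.94 and 29.9 CPM, and no knockout library exceeds 0.0587 CPM.

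In untreated cells, HOXA11 and the cell-cycle inhibitor CDKN1A were among the genes called higher in the knockout, and SOX21 among those called lower. HOXA11, a homeobox gene of posterior and limb patterning, stood at 64.6 ± 15.3 CPM in the knockout against 0.0632 ± 0.0339 CPM in the control (SD, n = 3 each; log2 fold change 9.86 ± 0.72 SE, edgeR adjusted p = 5.92e-05). CDKN1A, which encodes the CDK inhibitor p21, was 12.9-fold higher, at 549 ± 128 against 42.5 ± 12.5 CPM (edgeR adjusted p = 0.000167). SOX21, a neural progenitor factor, was 49.3-fold lower, at 0.398 ± 0.0818 against 19.8 ± 6.87 CPM (edgeR adjusted p = 0.00248).

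Each of the 4 HOX clusters held genes called higher in the untreated knockout, but none of the 4 lists passed with an estimated correlation. Of the 11 HOXA genes, 10 rose, and 11 when adjusted over the list alone; HOXA7 had a log2 fold change of 1.91 ± 0.76 SE (edgeR adjusted p = 0.0671). Among the called members, log2 fold changes were 9.86 for HOXA11, 9.27 for HOXA10, 7.53 for HOXA13, 6.67 for HOXA9, 6.21 for HOXA3, 5.66 for HOXA2, 4.32 for HOXA4, 4.27 for HOXA5 and 4.12 for HOXA6. The HOXA list was called by camera (adjusted p = 3.96e-13), with adjusted p = 0.096 with an estimated correlation. In the HOXB cluster 4 of 10 tested genes rose (5 adjusted over the list alone), among them HOXB9 by 4.21 and HOXB13 by 3.22 on the log2 scale (camera adjusted p = 0.000485, and adjusted p = 0.464 with an estimated correlation). In the HOXC cluster 5 of 6 tested genes rose, also 5 adjusted over the list alone, with 1 lower by that count (camera adjusted p = 0.000492, and adjusted p = 0.0591 with an estimated correlation). HOXC11 had no counts in the untreated control and was at least 378-fold higher in the knockout, taking 3 counts over the control group as the floor, and HOXC6 rose by 3.95 on the log2 scale. In the HOXD cluster 8 of 9 tested genes rose by either count, among them HOXD13, at 134 ± 67 against 20.8 ± 6.1 CPM, and HOXD9, 4.01-fold (camera adjusted p = 1.11e-06, and adjusted p = 0.073 with an estimated correlation). The HOX clusters hold antisense genes, and the sources used here do not say whether reads were counted by strand, so a HOX gene and its antisense partner may share counts.

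**Figure D2:**
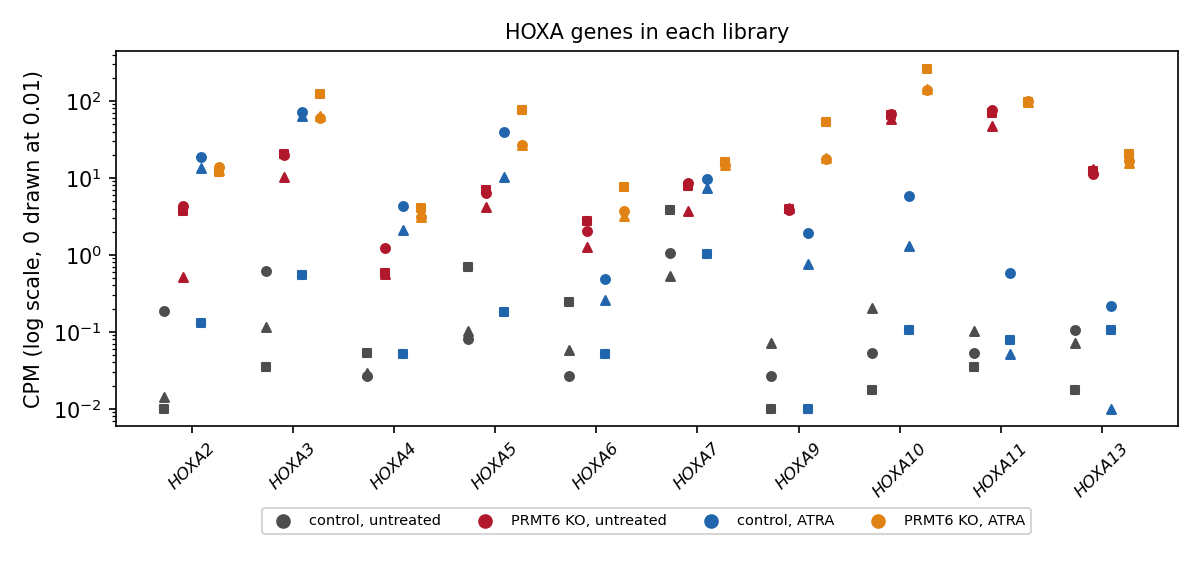
HOXA genes named in the text, in each library, in CPM on a log axis with 0 drawn at 0.01; colours give the 4 groups, and circles, squares and triangles replicates 1, 2 and 3, without error bars. HOXA11 averages 64.6 CPM in the untreated knockout and 98.1 CPM in the knockout with ATRA, against 0.0632 and 0.238 CPM in the matching controls.

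Some genes of other lineages were also higher in the untreated knockout. Of 19 tested mesoderm genes 7 rose and 2 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.027, and adjusted p = 0.329 with an estimated correlation). HAND2, a regulator of heart and limb mesoderm, rose by 8.39 ± 1.20 SE on the log2 scale, and EOMES, a regulator of mesendoderm, 22.2-fold. In the trophoblast and amnion list 5 of 12 tested genes rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.027, and adjusted p = 0.479 with an estimated correlation), with ISL1 16.5-fold and TP63 14.5-fold higher. The fibroblast list had 15 of 22 genes higher and none lower (17 adjusted over the list alone; camera adjusted p = 3.18e-08, and adjusted p = 0.337 with an estimated correlation). Of these genes 17 of 22 averaged at least 5 CPM in the untreated control, so the list does not mark fibroblasts alone. Within it COL6A1 was 4.02-fold higher, and FAP, a surface protease of activated fibroblasts, had a knockout-to-control ratio of 751 (95% counting interval 134 to 29700) on 1 control count. FAP stood at 6.64, 5.60 and 0.771 CPM in the knockout libraries, whereas COL6A1 stood at 641, 767 and 718 CPM. The endoderm list was not called (camera adjusted p = 0.0763; 4 of 13 genes higher and 1 lower, 5 and 1 adjusted over the list alone), although GATA4 was 56.2-fold and DAB2 3.21-fold higher.

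Some signalling targets and growth regulators also changed in the untreated knockout. Targets of TGF-beta, Nodal and BMP signalling had 12 of 22 genes higher and 2 lower (15 and 2 adjusted over the list alone; camera adjusted p = 4.3e-06, and adjusted p = 0.0915 with an estimated correlation), with ID1 2.62-fold higher. The p53 and CDK inhibitor list had 11 of 24 genes higher and 2 lower by either count (camera adjusted p = 7.71e-05, and adjusted p = 0.0583 with an estimated correlation). In it PHLDA3, a p53 target that restrains AKT signalling, rose 3.84-fold. Genes of retinoid signalling had 9 of 23 members higher and none lower by either count (camera adjusted p = 0.00138, and adjusted p = 0.464 with an estimated correlation). ALDH1A2, which makes retinoic acid, was 10.5-fold higher at 2.37 ± 1.01 CPM, and RDH10, which makes its precursor retinaldehyde, 7.30-fold. WNT targets had 6 of 22 genes higher and 1 lower by either count (camera adjusted p = 0.0297, and adjusted p = 0.464 with an estimated correlation), among them the WNT antagonist DKK1, 5.56-fold, and BAMBI, a pseudoreceptor that dampens TGF-beta signals, 3.17-fold.

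Neural progenitor regulators were the only list called lower in untreated cells, with 7 of 17 genes lower and none higher by either count (camera adjusted p = 0.0195, and adjusted p = 0.464 with an estimated correlation). Besides SOX21, FABP7 was 11.5-fold lower. SOX2, shared by pluripotent and neural progenitor cells, fell 3.49-fold, from 206 ± 64.4 to 59.0 ± 17.4 CPM. The pluripotency list had 3 of 27 genes higher, LEFTY1 8.10-fold among them, and 5 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.694). POU5F1 and NANOG, core pluripotency factors chosen after their values were seen, had log2 fold changes of 0.27 ± 0.64 and -0.03 ± 0.53 SE (edgeR adjusted p = 0.757 and 0.969). Among neuronal genes 5 of 24 were higher and 6 lower (5 and 8 adjusted over the list alone; camera adjusted p = 0.719, in the upward direction although the median was -0.38), with the neurofilament gene NEFM 5.41-fold and the synaptic gene SNAP25 6.89-fold higher. Neural crest genes were split, 4 higher and 4 lower of 18 by either count (camera adjusted p = 0.273, upward with a median of 0.50 and a mean of -0.21), with TWIST1 4.51-fold higher and PAX7 21.1-fold lower.

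The remaining lists were not called in untreated cells. Cell-cycle genes had 5 of 33 members higher and 10 lower (6 and 11 adjusted over the list alone; camera adjusted p = 0.654), with the mitotic kinase gene BUB1 4.80-fold and the cyclin gene CCNA2 2.49-fold lower. Cholesterol synthesis genes had 8 of 23 higher and 5 lower (9 and 6 adjusted over the list alone; camera adjusted p = 0.273), with MVD 2.06-fold higher and MSMO1 7.65-fold lower. Imprinted genes had 7 of 21 higher and 3 lower by either count (camera adjusted p = 0.0763), with DLK1 3.52-fold and NDN 2.74-fold higher. Of 35 Polycomb and trithorax genes 6 were higher and 9 lower (6 and 10 adjusted over the list alone; camera adjusted p = 0.883), and the Polycomb subunit genes PCGF6 and RBBP7 were 3.28-fold and 2.34-fold lower. The protein arginine methyltransferase list had 2 of 10 genes higher and 4 lower, PRMT6 included (3 and 4 adjusted over the list alone; camera adjusted p = 0.677), and NDUFAF7, a mitochondrial methyltransferase, was 3.43-fold lower. Epithelial genes had 2 of 21 higher and 5 lower by either count (camera adjusted p = 0.694), with the junction genes OCLN 5.44-fold and CLDN4 6-fold lower. Targets of FGF and ERK signalling had 3 of 19 higher and 2 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.582), with EPHA2 3.37-fold higher and FGFBP3 2.23-fold lower. Interferon-stimulated genes had 2 of 24 higher and 4 lower (0 and 3 adjusted over the list alone; camera adjusted p = 0.998), with DDX58 3.56-fold lower. Stress genes had 4 of 23 higher and 2 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.0763), with ATF4 1.78-fold and HSPA1A, which has a near-identical copy and is uncertain, 2.61-fold higher. Germline genes had 1 of 10 higher, NANOS3 6.23-fold, and 2 lower, TEX15 11.1-fold among them, by either count (camera adjusted p = 0.78). Of 13 mitochondrially encoded mRNAs 2 were lower, the overlapping MT-ND4 and MT-ND4L by 1.68-fold and 1.66-fold, and 0 adjusted over the list alone (camera adjusted p = 0.802).

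The largest changes in untreated cells by the rule for named genes also included single genes outside these groups. The hormone gene SST had a knockout-to-control ratio of 762 (95% counting interval 260 to 3700) on 3 control counts, and TBX2, a T-box repressor, was 212-fold higher. RBM12B had no counts in the untreated knockout and was at least 463-fold lower, from 16.9 ± 2.82 CPM. ZNF512 was 349-fold lower, ZNF486 113-fold, the meiosis gene MEIOB 94.6-fold and the somatostatin receptor gene SSTR1 79.0-fold lower.

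Across 19130 genes tested, edgeR called 6676 in untreated cells, 2480 higher and 4196 lower in the knockout, of which 5148 differed at least 2-fold. The 3 libraries of each group did not overlap for 9170 genes (47.9%), against 10% by chance if all libraries are independent. The near-identical knockout pair makes the chance share higher than 10%. In simulated data for this comparison the test recovered 62% of 50 genes changed 4-fold and 10% of 50 changed 2-fold, with 6 false calls among 18718 genes. Counting each near-identical knockout pair as 1 library left 1072 calls, and removing each library's GC trend left 3763. Without control untreated 3, knockout untreated 1 or knockout untreated 2 the calls numbered 3548, 3788 and 3058.

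With ATRA, HOXA11 and CDKN1A were again among the genes called higher in the knockout. HOXA11 stood at 98.1 ± 1.61 CPM in the knockout against 0.238 ± 0.3 CPM in the control (SD, n = 3 each; log2 fold change 8.73 ± 0.67 SE, edgeR adjusted p = 0.000106). CDKN1A stood at 612 ± 124 against 53.9 ± 12.1 CPM, 11.4-fold higher (edgeR adjusted p = 0.000266). The neurofilament genes NEFM and NEFL, markers of neurons, were 8.89-fold and 4.12-fold higher (edgeR adjusted p = 0.000266 and 0.000622). The neuronal list as a whole was not called (camera adjusted p = 0.764, in the upward direction although the median was -0.36 and 16 of 24 values were below 0), with 4 genes higher and 2 lower (5 and 6 adjusted over the list alone). PAX3, a neural crest and dorsal neural tube regulator, was 32.0-fold lower, at 0.556 ± 0.163 against 17.9 ± 4.52 CPM (edgeR adjusted p = 0.0347). The neural crest list was not called either (camera adjusted p = 0.93), with 1 of 18 genes higher and 2 lower by either count, and 8 values above and 10 below 0.

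Of the HOXA genes, 5 of 11 were called higher in the knockout with ATRA by either count: HOXA6, HOXA9, HOXA10, HOXA11 and HOXA13, with log2 fold changes of 4.18, 5.09, 6.24, 8.73 and 7.37. The anterior members HOXA2, HOXA3, HOXA4 and HOXA5 were not called, with log2 fold changes of 0.25, 0.86, 0.67 and 1.38, nor was HOXA7, with 1.32 (edgeR adjusted p = 0.905, 0.617, 0.626, 0.432 and 0.263). By limma-voom HOXA2, HOXA3, HOXA4 and HOXA5 had 2, 2.55, 2.07 and 3.2 and were not called either. The HOXA list was called (camera adjusted p = 5.08e-14), with adjusted p = 0.0554 with an estimated correlation. The HOXC list, with 4 of 6 genes higher (5 adjusted over the list alone), was called with both correlations (camera adjusted p = 1.55e-06, and adjusted p = 0.0103 with an estimated correlation). HOXC11 had no counts in the control and was at least 305-fold higher, and HOXC6 was 20.6-fold higher. In the HOXD list 5 of 9 genes rose (6 adjusted over the list alone), HOXD11 12.4-fold and HOXD13 8.47-fold among them (camera adjusted p = 4.46e-09, and adjusted p = 0.0603 with an estimated correlation). In the HOXB list 1 of 10 genes rose, HOXB9 13.7-fold, and 4 adjusted over the list alone (camera adjusted p = 0.000609, and adjusted p = 0.452 with an estimated correlation).

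The p53 and CDK inhibitor list was also called with both correlations in cells given ATRA (camera adjusted p = 6.35e-11, and adjusted p = 0.00233 with an estimated correlation), with 9 of 24 genes higher and 1 lower (12 and 2 adjusted over the list alone), PHLDA3 6.04-fold among them. Targets of TGF-beta, Nodal and BMP signalling had 5 of 22 genes higher and none lower (10 and 1 adjusted over the list alone; camera adjusted p = 1.52e-06, and adjusted p = 0.0682 with an estimated correlation), with LEFTY1 12.9-fold higher. The fibroblast list had 6 of 22 genes higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 3.35e-05, and adjusted p = 0.452 with an estimated correlation), with FAP 91.8-fold higher and S100A4 6.21-fold lower. FAP stood at 9.16, 0.822 and 8.62 CPM in the knockout libraries, the same library apart as for COL3A1. The WNT list had 3 of 22 genes higher and 1 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.0207, and adjusted p = 0.452 with an estimated correlation), with DKK1 14.0-fold and LGR5 4.73-fold higher. The trophoblast list had 1 of 12 genes higher, TP63 4.06-fold, and 4 adjusted over the list alone (camera adjusted p = 0.0207, and adjusted p = 0.452 with an estimated correlation). The stress list had 1 of 23 genes higher, HSPA1A, and 1 lower, NR4A1 (2 and 1 adjusted over the list alone; camera adjusted p = 0.0147, and adjusted p = 0.355 with an estimated correlation). Neural progenitor genes had 3 of 17 members lower and none higher by either count (camera adjusted p = 0.0207, and adjusted p = 0.452 with an estimated correlation), with SOX21 25.5-fold and LHX2 3.04-fold lower.

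Among the other named genes with ATRA, HAND2 was 79.8-fold, LMO2 3.60-fold, GATA4 22.6-fold, RDH10 5.83-fold, GDF3 5.92-fold, TWIST1 3.19-fold, EPHA2 2.62-fold, SPRY4 2.44-fold and NDN 1.83-fold higher in the knockout. CRABP1, which encodes a retinoic acid binding protein, was 3.27-fold lower, at 82.8 ± 3.98 against 270 ± 83.1 CPM. BUB1 was 3.48-fold, CCNA2 1.85-fold, HMGCS1 2.68-fold, CDKN1C 2.01-fold, TEX15 7.13-fold and TJP3 3.42-fold lower. SOX10, a neural crest factor, had a control-to-knockout ratio of 70.8 (95% counting interval 23.9 to 346) on 3 knockout counts. By size of change, EMC10 was 885-fold and MGP 586-fold higher, while RBM12B was 214-fold, ZNF512 213-fold, PKIB 54.5-fold and KLF2 26.3-fold lower. EMC10 stood at 110, 108 and 109 CPM in the knockout with ATRA and at most at 0.215 CPM in the matching controls, but at 0.160, 45.9 and 26.4 CPM in the untreated controls. MGP stood at 51.0, 0.117 and 51.0 CPM in the knockout libraries.

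With ATRA, edgeR called 1437 of 19130 genes, 626 higher and 811 lower in the knockout, of which 1259 differed at least 2-fold. The groups did not overlap for 6623 genes (34.6%), against 10% by chance for independent libraries, a share that the near-identical knockout pair makes higher. In simulated data for this comparison it recovered 62% of 50 genes changed 4-fold and 4% of 50 changed 2-fold, with 7 false calls among 18777 genes. Counting each near-identical pair as 1 library left 71 calls, among them PRMT6, HOXA10, HOXA11, HOXA13, HOXC11, HOXD11, HOXD13, CDKN1A, PHLDA3, NEFM, NEFL, EMC10, RBM12B and ZNF512 but none of the other genes named for this comparison. The calls numbered 241, 831 and 219 without knockout ATRA 1, 2 or 3, 632 without control ATRA 2, and 843 and 820 without knockout untreated 1 or 2, while DESeq2 called 2935, a fit of only the compared groups 768 and edgeR with no filter on low counts 2317.

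The knockout difference was alike in direction in both states. Of the genes called, 1054 were called in both comparisons with the same sign, 461 higher (HOXA11, HOXA13, CDKN1A and NEFM among them) and 593 lower (PRMT6, RBM12B and ZNF512 among them), and 0 with opposite signs. Independent lists of these sizes would share 81.2 higher and 178 lower genes. These comparisons share no library, and their log2 fold changes correlated at r = 0.72 across genes, which are not independent replicates. They do share 1 knockout line and the GC trend linked to genotype, with knockout libraries at 0.223 to 0.617. Deviations of knockout untreated 3 and knockout ATRA 2 from their group means also correlated at 0.58. Part of the agreement may come from these links, and it was not computed with the GC trend removed. The number called in both was 187 and 201 without knockout ATRA 3 or 1, 453 without control ATRA 2, 652 without knockout ATRA 2, 529 and 504 without knockout untreated 1 or 2, and 1625 without control ATRA 3.

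In control cells, METRN, which encodes the glial and neuronal differentiation factor meteorin, and the homeobox gene PRRX2 were called higher with ATRA. PHC1, a Polycomb subunit gene, was called lower. No gene was called with only the compared groups in the fit, with the near-identical knockout libraries summed, or without control untreated 2 or 3. DESeq2 called 1679 genes and limma-voom 30. Another split of the same libraries gave 5344 calls, against 22 as labelled. METRN stood at 217 ± 76.5 CPM with ATRA against 27.6 ± 3.70 CPM untreated (SD, n = 3 each; log2 fold change 2.97 ± 0.34 SE, edgeR adjusted p = 0.0121). PRRX2 stood at 118 ± 14.7 against 31.3 ± 4.83 CPM (edgeR adjusted p = 0.0118), and PHC1 at 89.5 ± 16.4 against 346 ± 170 CPM (edgeR adjusted p = 0.0441). The other named genes that rose were PKDCC 4.02-fold, GPR162 3.52-fold, BCL7C 3.5-fold and TAX1BP3 2.98-fold, and those that fell were the long noncoding RNA gene MIAT 11.3-fold and the protease gene CTSK 3.46-fold.

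CYP26A1 and HOXA3 were high in only part of the control libraries given ATRA. CYP26A1, the retinoic acid hydroxylase and a direct target of retinoic acid receptors, chosen after its values were seen, stood at 256, 0.0520 and 12.4 CPM with ATRA against 0.0267, 3.2 and 0.0433 CPM untreated (edgeR adjusted p = 0.173). HOXA3 stood at 70.8, 0.546 and 64.6 CPM with ATRA (log2 fold change 7.62, edgeR adjusted p = 0.057), so control ATRA 2 lacked the high level of both HOXA3 and CYP26A1. Its METRN, at 185 CPM, lay between the 304 and 161 CPM of the other control libraries given ATRA. The rule that named METRN asked for groups that do not overlap, so its METRN is no sign of a response in that library.

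**Figure D3:**
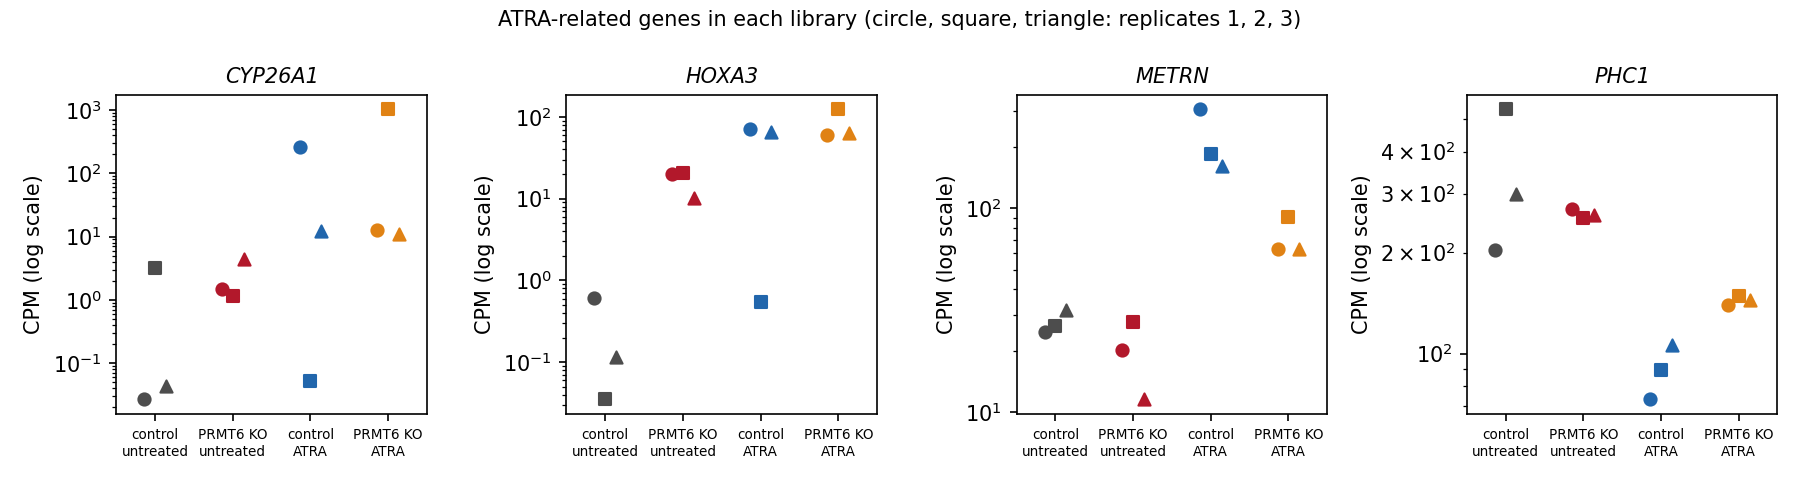
CYP26A1, HOXA3, METRN and PHC1 in each library, in CPM on log axes; colours give the 4 groups, and circles, squares and triangles replicates 1, 2 and 3, without error bars. Control ATRA 2 stands at 0.0520 CPM for CYP26A1 and 0.546 CPM for HOXA3, against 256 and 70.8 CPM in control ATRA 1. Its METRN of 185 CPM is above every untreated library, which the rule that named METRN required for the untreated controls.

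As groups, 8 lists were called with ATRA in control cells, none of them with an estimated correlation. The pluripotency list was lower (camera adjusted p = 7.49e-10, and adjusted p = 0.349 with an estimated correlation), with 0 of 27 genes called over all genes and 1 higher and 14 lower adjusted over the list alone. Its members NANOG, POU5F1 and DNMT3B, chosen after their values were seen, had log2 fold changes of -2.92, -1.13 and -1.54 (edgeR adjusted p = 0.057, 0.338 and 0.0619). The germline list was lower as well (camera adjusted p = 0.028, and adjusted p = 0.349 with an estimated correlation), with 1 gene higher and 1 lower adjusted over the list alone. Retinoid signalling genes were higher (camera adjusted p = 1.55e-08, and adjusted p = 0.349 with an estimated correlation), with 11 of 23 higher adjusted over the list alone. So were the HOXA list, with 7 of 11 (camera adjusted p = 1.29e-07, and adjusted p = 0.349 with an estimated correlation), and the HOXB list, with 8 of 10 (camera adjusted p = 7.34e-05, and adjusted p = 0.553 with an estimated correlation). Trophoblast genes were higher with 6 of 12 (camera adjusted p = 7.67e-05, and adjusted p = 0.349 with an estimated correlation), imprinted genes with 3 of 21 (camera adjusted p = 0.00179, and adjusted p = 0.349 with an estimated correlation), and fibroblast genes with 0 of 22 (camera adjusted p = 0.0338, and adjusted p = 0.652 with an estimated correlation). No member of these lists was called over all 19130 genes by edgeR.

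For ATRA in control cells, edgeR called 22 genes, 19 higher and 3 lower, each at least 2-fold, and 3961 had an unadjusted p under 0.05 against 956 by chance. The groups did not overlap for 2837 genes (14.8%), against 10% by chance. In simulated data for this comparison it recovered 54% of 50 genes changed 4-fold and 8% of 50 changed 2-fold, with 8 false calls among 18694 genes. The calls numbered 2457 without control untreated 1, 0 without control untreated 2 or 3, 2, 2419 and 12 without control ATRA 1, 2 or 3, 3, 2 and 3 without knockout untreated 1, 2 or 3, and 2, 5 and 2 without knockout ATRA 1, 2 or 3. They numbered 1903 without control untreated 2 and control ATRA 2 together, 14 with the GC trend removed, 0 with each near-identical knockout pair counted as 1 library, 1679 by DESeq2, 30 by limma-voom, 0 with only the compared groups in the fit and 1407 with no filter on low counts.

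In knockout cells, CLDN4, a tight junction gene, and DSTN, which encodes the actin-severing protein destrin, were called higher with ATRA. No gene was called with each near-identical pair counted as 1 library or by limma-voom. CLDN4 stood at 19.5 ± 6.77 CPM with ATRA against 1.59 ± 0.472 CPM untreated (SD, n = 3 each; log2 fold change 3.61 ± 0.52 SE, edgeR adjusted p = 0.0456), and DSTN at 165 ± 5 against 71.2 ± 5.5 CPM (edgeR adjusted p = 0.0456). TMED7 and NDUFC2 were 7.65-fold and 4.76-fold higher (edgeR adjusted p = 0.0414 for each); both share exons with annotated read-through genes, so their counts are uncertain. HOXA11 was already high in untreated knockout cells and had a log2 fold change of 0.60 ± 0.45 SE with ATRA (edgeR adjusted p = 0.693).

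As groups in the knockout with ATRA, the pluripotency list was lower (camera adjusted p = 7.03e-10, and adjusted p = 0.492 with an estimated correlation), with 1 gene higher and 6 of 27 lower adjusted over the list alone. Retinoid signalling genes were higher, with 3 of 23 higher adjusted over the list alone (camera adjusted p = 0.000545, and adjusted p = 0.507 with an estimated correlation), as were HOXA genes with 0 of 11 (camera adjusted p = 8e-05, and adjusted p = 0.492 with an estimated correlation) and HOXB genes with 4 of 10 (camera adjusted p = 8.03e-05, and adjusted p = 0.507 with an estimated correlation). Epithelial genes were higher, with CLDN4 called over all genes and 3 of 21 higher adjusted over the list alone (camera adjusted p = 0.000117, and adjusted p = 0.492 with an estimated correlation). The p53 and CDK inhibitor list was higher with both correlations (camera adjusted p = 0.000117, and adjusted p = 0.0424 with an estimated correlation), with 21 of 24 log2 fold changes above 0 and 1 gene higher adjusted over the list alone. Trophoblast genes, 2 of 12 adjusted over the list alone (camera adjusted p = 0.000247, and adjusted p = 0.492 with an estimated correlation), and mitochondrial mRNAs, 0 of 13 (camera adjusted p = 0.0421, and adjusted p = 0.576 with an estimated correlation), were higher. Lower were fibroblast genes, 0 of 22 adjusted over the list alone (camera adjusted p = 0.0183, and adjusted p = 0.595 with an estimated correlation), cell-cycle genes, 0 of 33 (camera adjusted p = 0.0271, and adjusted p = 0.576 with an estimated correlation), and WNT targets, 1 of 22 (camera adjusted p = 0.0361, and adjusted p = 0.512 with an estimated correlation).

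For ATRA in knockout cells, edgeR called 6 genes, 5 higher and 1 lower, each at least 2-fold, and 2233 had an unadjusted p under 0.05 against 956 by chance. The groups did not overlap for 6109 genes (31.9%), against 10% by chance for independent libraries. Both groups hold a near-identical pair, which makes the chance share higher, so no excess can be read from this. In simulated data for this comparison it recovered 58% of 50 genes changed 4-fold and 4% of 50 changed 2-fold, with 12 false calls among 18773 genes. The calls numbered 76, 21 and 2 without control untreated 1, 2 or 3, 181 without control ATRA 2, and 0 without any other single library. They numbered 571 without control untreated 2 and control ATRA 2 together, 0 with each near-identical pair counted as 1 library, 0 by limma-voom, 539 by DESeq2, 1336 with only the compared groups in the fit and 272 with no filter on low counts. None of the 22 genes called in the control was called in the knockout by edgeR, 21 of them had the same sign there, and fold changes correlated at r = 0.42 across genes, where independent lists would share 0.00497 higher genes. That number was 14 without control untreated 1 and 119 without control ATRA 2.

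Whether the knockout changed the ATRA response was asked of the interaction, the ATRA effect in the knockout less that in the control. No HOXA gene passed: the interaction log2 values ran from -5.41 ± 1.86 SE for HOXA2 and -5.35 ± 1.65 SE for HOXA3 to 0.06 ± 1.55 SE for HOXA6 (edgeR adjusted p = 0.509, 0.509 and 0.991). As groups, the fibroblast list was lower in the interaction (median -1.14, 21 of 22 values below 0; camera adjusted p = 8.17e-05, and adjusted p = 0.695 with an estimated correlation). So were the HOXA list (median -2.04, 10 of 11 values below 0; camera adjusted p = 0.00257, and adjusted p = 0.695 with an estimated correlation) and the retinoid list (median -0.46, 20 of 23 values below 0; camera adjusted p = 0.0115, and adjusted p = 0.695 with an estimated correlation). No member of these lists was called by edgeR over all genes or adjusted over the list alone.

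By edgeR 0 genes were called in the interaction, 1868 had an unadjusted p under 0.05 against 956 by chance, and the smallest adjusted p was 0.509. DESeq2 called 13 and limma-voom 0. In simulated data for this comparison edgeR recovered 16% of 50 genes with a 4-fold and 82% of 50 with a 16-fold interaction, with 4 false calls among 18745 genes. The calls numbered 135 without control untreated 1, 2 without control ATRA 2, 8 without control untreated 2 and control ATRA 2 together, and 8 with no filter on low counts.

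The knockout effect in untreated cells was set beside the ATRA effect in control cells, which share the untreated control libraries. Of the 22 genes called with ATRA, 9 were also called higher in the knockout and 0 lower, against 2.46 and 0.658 for independent lists, which do not allow for the shared controls. Simulated unchanged groups with the shared controls had a mean of 0 genes called in both. Unchanged groups leave few genes to call in either comparison, so this does not test the overlap. The fold changes correlated at r = 0.527 across genes, where 15 simulations of unchanged groups with the shared controls gave 0.484 ± 0.011 (SD), and their covariance was 0.662 against a simulated 0.114, a difference of 0.549. The simulated libraries were independent draws without near-identical pairs or GC trends, so their spread may be smaller than that of the real libraries. The 3 control libraries are too few to split, so part of the covariance difference may come from them. HOXA3 had log2 fold changes of 6.21 in the knockout and 7.62 with ATRA (the latter with edgeR adjusted p = 0.057), whereas HOXA11 had 9.86 in the knockout and 1.73 with ATRA (the latter with edgeR adjusted p = 0.225).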

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

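For the patterns below, the tests of fewer copies of chromosome parts, of the stretches found again with the GC trend removed and of a mislabelled sample were chosen after the result was seen, and so were the ratios of calls without single libraries and by other settings and the alternatives without the GC trend, without 2 control libraries and with thinned libraries.

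In the interaction, the ATRA effect in the knockout less that in the control, camera called 3 lists lower relative to other genes: the fibroblast list (adjusted p = 8.17e-05), the HOXA list (0.00257) and the retinoid list (0.0115). None passed with an estimated correlation (adjusted p = 0.695 for each) or by fry, which tests a list against no change (adjusted p = 0.671 for each). Of 40 splits of the libraries, the real one included, 34 gave at least 3 lists, with up to 13 in another. These splits mixed the genotypes freely, so the genotype difference enters them and they do not test chance for the lists. Chance therefore stays open for the lists. For genes in the interaction the real count was 0, so that all 40 of 40 splits gave at least as many says nothing; the highest other counts, 2241 and 709, were the only ones above 0, which points to a structure of the samples.

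The lack of a rise of HOXA3 and CYP26A1 in control ATRA 2 was weighed. On 100 genes ranked in the knockout libraries alone, with 0 for untreated controls and 1 for the other ATRA controls, this library sat at 0.60 (95% bootstrap interval over genes 0.49 to 0.73), where an untreated culture would sit near 0. With the GC trend removed it sat at 0.35 (0.27 to 0.44), which argues against GC content as the cause, since removing the trend moved the library away from the other ATRA controls. The untreated controls sat at -0.47, 0.13 and 0.25, or at 0.04, -0.07 and 0.02 with the GC trend removed. So on these genes no untreated library sat with the ATRA controls. Over all genes, the split that exchanged control untreated 1 with control ATRA 2 gave 5344 calls, against 22 as labelled. On the 100 genes, however, control untreated 1 sat at -0.47, while control ATRA 1 and 3 sat at 1.56 and 0.99. With the GC trend removed these were 0.04, 1.55 and 1.41. This argues against a swap of the pair. CYP26A1 in control untreated 1 was also only 0.0267 CPM. For control ATRA 2, the interval of 0.49 to 0.73 lay above the bound set for an untreated culture. It reached just below the bound set against one, so a mislabelled culture stays undecided. A weakly treated culture cannot be told apart here from a slower response, because no test separated them, and a biological cause was not tested.

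Genes in parts of chromosomes 2 and 3 were lower in the knockout libraries: in stretches found in untreated libraries, the median with the GC trend removed was -0.26 (-0.31 to -0.21), and 74.8% of genes (72.4 to 77.2) were below the median gene with ATRA, neither of which decides. As they lay on many chromosomes and followed GC content, stretches were found again in the ATRA libraries with the GC trend removed, which left ACP1 to POLR2D on chromosome 2 (400 genes) and TRNT1 to ARL6IP5 on chromosome 3 (300 genes). There the untreated median with the GC trend removed was -0.41 (-0.47 to -0.36), which argues against GC content as the whole cause, and 77% of genes (73.9 to 80) were lower. In the untreated libraries, which were not used to find these stretches, the controls stood at 0.31, 0.14 and 0.17 and the knockout at -0.25, -0.25 and -0.24. Fewer copies of these parts in the knockout line may account for this, but RNA alone cannot tell it apart from other regulation of neighbouring genes, and a single knockout line carries it with the genotype.

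The untreated comparison of knockout and control had 4.65 times the calls of that with ATRA, a ratio that moved with single libraries: 2.55 and 2.9 without control untreated 2 or 3, 12.5 without control ATRA 2, and 24, 7.88 and 26.2 without knockout ATRA 1, 2 or 3. It was 2.64 by DESeq2, 2.88 with no filter, 7.15 for the compared groups alone, 7.58 with the replicate block and 15.1 with near-identical libraries summed. Thinned to equal totals it was 4.78, which argues against depth as the cause, and with the GC trend removed 2.63, between the bounds set for it, so GC content may account for part. Without control untreated 2 and control ATRA 2 together it was 5.59, past the bound set beforehand, but that bound did not foresee that they act in opposite directions, so their part in it stays open. A smaller effect of the knockout with ATRA stays open: edgeR called 0 genes in the interaction, DESeq2 13 and limma-voom 0, but 1868 had an unadjusted p under 0.05 against 956 by chance, and simulated recovery at 4-fold was 16%. The fibroblast and HOXA lists were higher in the untreated knockout by camera (adjusted p = 0.337 and 0.096 with an estimated correlation). They had 21 of 22 and 10 of 11 interaction values below 0 (camera adjusted p = 8.17e-05 and 0.00257, and 0.695 for each with an estimated correlation). The interaction subtracts the untreated difference, so the same libraries push lists that are high there below 0. These signs therefore decide nothing.

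For the other comparisons the 6 libraries make 10 splits, too few for a share under 0.05; the numbers of splits as large count the real one. Knockout against control gave 6676 genes untreated (highest other split 0; 1 split as large) and 1437 with ATRA (highest other 1; 1 split as large), and 12 and 11 lists (highest other 14 and 11; 4 and 5 splits as large). ATRA against untreated gave 6 genes in the knockout (highest other 0; 1 split as large) and 11 lists (highest other 11; 2 splits as large). In the control it gave 22 genes and 8 lists (highest other 5344 and 14; 2 and 4 splits as large). The split with 5344 genes set control untreated 1 with control ATRA 1 and 3 against control untreated 2 and 3 with control ATRA 2. That is the labelled grouping with control untreated 1 and control ATRA 2 exchanged. It points to a structure of the control libraries other than ATRA as labelled. The sides of this split also differed in their correlation with GC content. Control untreated 1 and control ATRA 1 and 3 stood at -0.298, -0.294 and 0.097. Control untreated 2 and 3 and control ATRA 2 stood at -0.407, -0.496 and -0.403. Whether GC content accounts for these calls was not tested.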

How the results depend on the processing

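The GC trend, summed, thinned and 2-libraries-out settings were chosen after the data were seen; for values that changed, the cause was not tested. In order of knockout untreated, knockout with ATRA, ATRA in control, ATRA in knockout and interaction, genes called numbered 6676, 1437, 22, 6 and 0. They were 7758, 2935, 1679, 539 and 13 by DESeq2, which also made more false calls in simulated data; 6440, 1015, 30, 0 and 0 by limma-voom; 6668, 2317, 1407, 272 and 8 with no filter; 5489, 768, 0 and 1336 for the compared groups alone; 3763, 1432, 14, 8 and 0 without the GC trend; 1072, 71, 0, 0 and 0 with near-identical libraries summed; and 7369, 1319, 1903, 571 and 8 without control untreated 2 and control ATRA 2. RLE scaling, the stricter filter, a log2 fold change of at least 1 and thinning kept each count within 1.5 times. Leaving out each library gave 3058 to 8453, 219 to 2129, 0 to 2457, 0 to 181 and 0 to 135; genes shared by both knockout comparisons numbered 187 to 1625, and by both ATRA comparisons 0 to 119. The correlation of knockout and ATRA effects was 0.54 with the stricter filter.

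Lists called numbered 12, 11, 8, 11 and 3. They were 0, 2, 0, 1 and 0 with an estimated correlation, 10, 6, 0, 1 and 0 by fry, which tests whether a list moves without comparing it with other genes, and 7 in the interaction without control untreated 2 and control ATRA 2.

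With the replicate number as a block, genes called were 5772, 761, 4, 0 and 0, and lists called 13, 13, 10, 11 and 4. The numbers did not pair the libraries: of 18 same-numbered pairs 3 had deviations correlated over 0.1 (range -0.49 to 0.39), and 5 of 12 libraries matched their own number best. Some pairs with unlike numbers correlated more, knockout untreated 3 with knockout ATRA 2 at 0.58 and control untreated 1 with control ATRA 3 at 0.49. Others were as low as -0.49, as for knockout untreated 3 with knockout ATRA 1. The fits do not allow for such links across ATRA.

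Of 132 called values of named genes, none changed direction. Between 0 (no filter) and 64 (near-identical libraries summed) lost their call, and 2 to 32 on leaving out 1 library. With the GC trend removed 21 lost their call. They are not listed here, so the call of a single named gene may depend on the GC trend. In untreated cells the summed setting ended the calls of HOXA2, HOXA4, HOXA5, HOXB13, SOX2, PAX7, PCGF6, SSTR1, ATF4, BAMBI, DDX58, FGFBP3, MT-ND4 and MT-ND4L. Only values not called changed sign. On leaving out each library, HOXA2 with ATRA ranged from -0.33 to 0.9 (2 by limma-voom), HOXA11 and HOXA13 under ATRA in control from -0.02 to 2.32 and from -0.24 to 1.3, and PRMT6 under ATRA in the knockout from -3.1 to 0.23. The interaction ranged from -1.71 to 0.62 for HOXA11, from -0.8 to 0.78 for HOXA13 and from -1.19 to 0.81 for HOXA6. Without control untreated 2 and control ATRA 2 together, HOXA2 with ATRA was -0.33 and the interaction 0.32 for HOXA13 and -1.68 for HOXA6. HOXA13's interaction was 0.37 by limma-voom, and HOXA6's -0.19 with the replicate block. Depth limits genes near 3 counts per library; at 2-fold, simulated recovery for knockout untreated was 10%.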

Other observations

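The ATRA response of the pluripotency genes was also read gene by gene; the genes of this part were chosen after their values were seen, and no test was added. DNMT3B, the de novo DNA methyltransferase of pluripotent cells, stood at 613, 576 and 442 CPM in the untreated control and at 109, 286 and 165 CPM with ATRA, and at 466, 479 and 702 CPM in the untreated knockout and 153, 252 and 152 CPM with ATRA. Its log2 fold change with ATRA was -1.54 ± 0.34 SE in the control and -1.57 ± 0.34 SE in the knockout (edgeR adjusted p = 0.0619 and 0.112), with an interaction of -0.02 ± 0.47 SE (edgeR adjusted p = 0.989). NANOG stood at 46.9, 109 and 65.8 CPM in the untreated control, 2.83, 18.1 and 8.35 CPM in the control with ATRA, 55.6, 58.7 and 103 CPM in the untreated knockout and 25.8, 42.2 and 25.3 CPM in the knockout with ATRA. Its interaction was 1.70 ± 0.75 SE (edgeR adjusted p = 0.509). Control ATRA 2, which had a low CYP26A1, had the highest NANOG, DNMT3B and POU5F1 of its group, the last at 895 CPM against 147 and 148 CPM.

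CYP26A1 also differed between the knockout libraries with ATRA, at 12.7, 1020 and 11 CPM, the middle value being that of knockout ATRA 2, the library with low COL3A1.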
